A study of Mus musculus with 3 samples.

How the data were processed

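Total RNA of 3 mouse organoid cultures was extracted with the mirVana kit and labelled with Hy5 by the miRCURY LNA labelling kit, per the labels' protocols; the cultures grew in Matrigel in serum-free medium with R-spondin 1, EGF and Noggin. Per the file headers, each array was scanned at 635 nm at 3 gains, and the deposited scanner intensity is the median brightness of a spot with no background subtracted. The authors' value table holds an intensity that was found from the values to be the spot median minus the trimmed mean of the blank spots, divided by 1 factor per array so that the listed values have a median of 25 (a straight line fitted each array with a largest residual of 6.2e-06). It is on a linear scale, with no centring by gene. The array platform, scanner software and microRNA database release are not given in the sources used here.

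Groups were taken from the sample titles, 1 array in each. Probe spots marked as bad at any gain were left out, which removed 2 probes on the wild-type array. Control and blank spots so marked were kept, 4, 17 and 29 on the wild-type, tumour and treated arrays. limma 3.58.1 in R 4.3.3 corrected the background by normexp fitted on the 1664 blank spots with an offset of 50, and the 1265 probes were quantile normalized across the 3 arrays and put on the log2 scale. Control and blank spots were left out of the normalization. A probe was called detected when its spot exceeded the blank mean plus 2 SD, with 5% of blanks trimmed at each end. Blank means were 27.3, 29.5 and 22.7 on the wild-type, tumour and treated arrays, with SDs of 0.901, 1.14 and 0.750.

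The fixed plan, from which this departs, named the per-spot background column for normexp and the blank spots only where no such column existed. The column exists, but it follows the signal of its own spot (r = 0.99, 0.99 and 0.98 on the log scale) and takes 63.9%, 76.5% and 35.8% of each unit of signal on the 3 arrays. The blank spots were therefore used, a choice made after these properties were seen and before any difference between arrays was computed. Results with the planned column are given as an alternative, and several named probes change sign under it.

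With 1 array per group there was no test. Probes with a log2 difference of at least 2-fold were counted if detected on at least 1 of the 2 arrays compared. A probe detected on 1 of them has only a lower bound on its difference. The offset of 50 compresses differences of dim probes. Spike control spots (8 of each kind per array) averaged 8030 ± 464, 7951 ± 801 and 5007 ± 339 (SD) for the first kind. The precision between arrays is limited by their number.

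There were 19 fixed microRNA lists, written before the data were examined. A list's median was set among the medians of 10000 random lists matched in 10 expression bins, as a description of these arrays. When the step was tested, 11 of 200 unshifted random lists of 15 probes (5.5%) fell outside the middle 95%. This share holds for randomly drawn probes, not for families or clusters, whose members may share signal or locus. The rule for named probes took, per comparison, the 10 largest differences in each direction among probes detected on both arrays whose higher signal was at or above the median of such probes, the 3 largest bounds in each direction, up to 4 members of lists outside the middle 95%, all detected members of the list of miR-192, miR-194 and miR-215, and the 10 brightest probes of each array. Gene neighbours were taken from RefSeq on GRCm38.p6, with a distance limit of 10000 bases between neighbours. Of 1252 probes that name a single mature sequence, 1139 matched a RefSeq gene by symbol.

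The steps were tested on simulated data in which the 3 arrays differ by spot noise alone. In 100 such draws of 1265 probes no probe reached 2-fold, and the largest log2 difference was 0.58 in tumour against wild type and 0.51 in treated against untreated. With 200 changed probes simulated in tumour against wild type, 19 of 20 bright and 24 of 80 dim probes with a true log2 difference of 2 or 3 were found at 2-fold. Spot noise leaves out differences between cultures, RNA extractions and hybridisations.

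The alternatives fixed in advance were an offset of 16, plain subtraction of the blank mean, scaling to the median of commonly detected or of all probes, a limit of 3 SD, detection on every array compared, the authors' values and a 1.5-fold threshold. Chosen after seeing the data were the brightest negative control as the detection limit, scaling to the spike controls and the per-spot background column as an alternative. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps. Probe sequences were not used here, so cross-hybridisation and base composition were not tested.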

Results

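MicroRNA levels were measured on 3 single-colour microarrays of mouse intestinal organoids, which are small epithelial structures grown in a gel from stem cells. The first array held RNA from organoids of normal intestinal epithelium of wild-type mice. The second held RNA from organoids grown out of intestinal tumours of ApcMin mice, which carry a germline truncation of the tumour suppressor Apc. The third held RNA from such tumour organoids exposed to 1 uM 5-Aza-CdR (decitabine), an inhibitor of DNA methyltransferases. Each group had 1 array, so no difference reported here has a replicate check, no p-value is given, and the array and the group cannot be told apart.

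Each array carried 1265 microRNA probes at 1 spot each. Signal stood above the detection limit for 954 probes on the wild-type array, 959 on the tumour array and 914 on the treated tumour array, and 817 probes were detected on all 3. Many of these were close to background: 413, 410 and 408 probes, in the same order, were brighter than the brightest negative control spot of their array. The 10 brightest probes held 56.8%, 48.9% and 50.2% of the detected signal. miR-2137 was the brightest on every array, with 16%, 11.8% and 14.2% of the signal, and miR-5126, miR-5100, miR-3968, miR-2861, miR-6366, miR-3960 and miR-5109 were among the 10 brightest on all of them. Across probes detected on at least 1 array, the normalized log2 signals correlated at r = 0.97 between wild-type and tumour organoids and at r = 0.99 between untreated and treated tumour organoids. Probes are not independent replicates.

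The first comparison asked which microRNAs differ between tumour and wild-type organoids. The largest difference was that of miR-215-5p, a microRNA of the intestinal epithelium, whose signal above blank was 1241 in wild-type organoids and 33.4 in tumour organoids, a normalized log2 difference of -4.22 (-5.72 to -2.48 over the settings). miR-194-5p and miR-192-5p, which are encoded in clusters with each other and with miR-215, were lower in tumour organoids by log2 differences of -2.60 and -2.44. The related probes miR-378a-3p, miR-378c, miR-378b and miR-378d were also lower, at -1.67, -1.58, -1.33 and -1.24. In the other direction, miR-3473e, miR-3473a and miR-3473b were higher in tumour organoids by 2.38, 2.18 and 2.11, and miR-23b-3p and miR-23a-3p by 1.69 and 1.13. Members of the miR-378, miR-23, miR-3473 and miR-192/miR-215 families resemble one another in sequence, so their probes may share signal and single members are uncertain.

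In all, 13 of 1040 probes were at least 2-fold higher and 14 at least 2-fold lower in tumour organoids. The other higher probes were miR-5128 (1.66), miR-712-3p (1.46), miR-5129-5p (1.25), miR-1906 (1.20), miR-6244 (1.16), miR-1934-3p (1.13), miR-290-5p (1.11) and miR-29a-3p (1.01). The other lower probes were miR-710 (-1.79), miR-6236 (-1.77), miR-3067-3p (-1.74), miR-711 (-1.67), miR-3072-5p (-1.17), miR-365-1-5p (-1.04) and miR-215-3p (-1.04). In tumour organoids miR-215-3p was only 2.75 above blank, just over the detection limit and under the brightest negative control, so the size of its difference is uncertain (-4.77 with the blank mean subtracted). miR-1934-3p, miR-378d, miR-3072-5p and miR-365-1-5p lie outside the rule for named probes and are given because they complete the count. Of the 1040 probes, 169 were detected on 1 of the 2 arrays. The largest lower bound on any of their differences was 1.15-fold, that of miR-340-5p, which was higher in tumour organoids. With the blank mean subtracted its difference was 5.33-fold, so these bounds do not exclude large differences. The count of higher and lower probes was 22 and 11 with arrays scaled to the median of commonly detected probes, 32 and 10 with the median of all probes, 37 and 9 with the spike controls, and 55 and 35 in the authors' values. With the per-spot background column of the files, which the fixed plan had named and which was set aside because it follows the spot's own signal, the counts were 20 and 27, only 4 of the 13 higher and 4 of the 14 lower probes remained 2-fold different, and 4 of the higher and 5 of the lower probes took the opposite sign, among them miR-192-5p, miR-378c, miR-378b, miR-215-3p, miR-23a-3p, miR-23b-3p and miR-3473b.

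**Figure D1:**
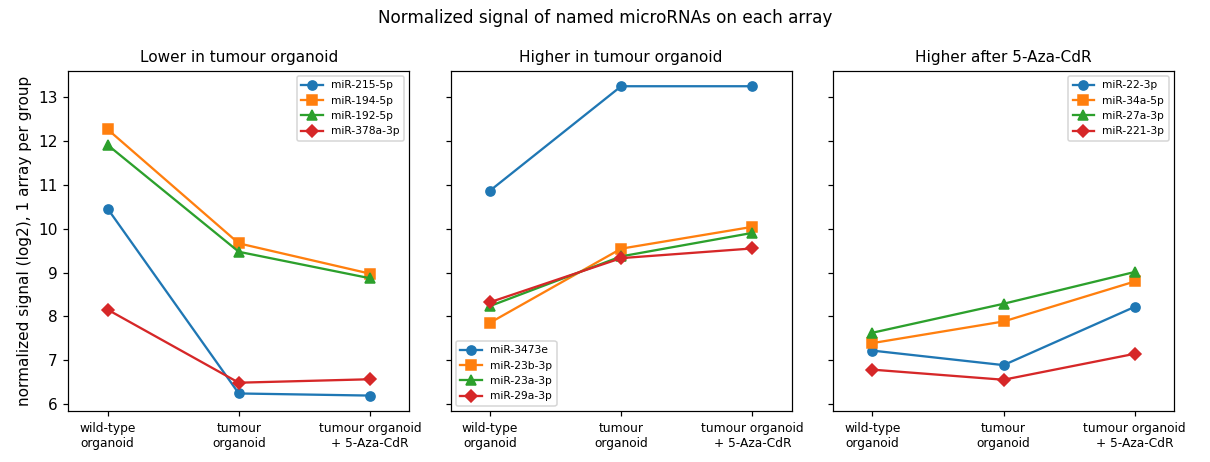
Normalized log2 signal of 12 microRNA probes on the 3 arrays, 1 array per group, with 1 point per array and lines joining the same probe. miR-215-5p, miR-194-5p and miR-192-5p were lower on both tumour arrays than on the wild-type array, and miR-22-3p and miR-34a-5p were highest on the treated array; with the per-spot background column miR-192-5p was not lower in untreated tumour organoids (0.16).

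All 7 detected probes of the list of miR-192, miR-194 and miR-215 were lower in tumour organoids, 4 of them at least 2-fold, with a median log2 difference of -1.04, under the middle 95% of matched random lists (-0.21 to 0.23). They ranged from miR-215-5p at -4.22 to miR-194-2-3p at -0.13. This list was fixed with knowledge of earlier work on these microRNAs in intestinal tumour organoids, so its direction is not independent evidence, and its median was 0.021 with the per-spot background column. The list of p53-induced microRNAs (median -0.17, 12 of 15 probes lower) also holds these microRNAs, beside miR-107-3p (-0.88) and miR-16-5p (-0.63). It therefore partly repeats the list of miR-192, miR-194 and miR-215 and is not a separate result. Its higher probes numbered 3, among them miR-34a-5p (0.49). Other lists outside the middle 95% of random lists had small medians. The miR-17-92 cluster and its paralogues, which MYC induces, had a median of -0.07 with 18 of 25 probes lower, including miR-20a-5p (-0.67), miR-20b-5p (-0.60) and miR-17-5p (-0.50), and the median turned to 0.074 under spike scaling, where all probes shifted and the list stayed under the random range (percentile 0.845). This list lay within the range in the authors' values (percentile 2.92) and with the per-spot background column (12.4). The pluripotency clusters miR-290 and miR-302 had a median of -0.039 with 12 of 17 lower, including miR-291b-5p (-0.52), while miR-290-5p was higher, and the median turned to 0.038 under spike scaling; this list lay outside the random range in only 1 of 10 other settings. Blood-cell microRNAs had a median of 0.08 with 9 of 10 higher, none of them 2-fold; only 3 of the 10 were brighter than the negative controls, and over these the list lay within the random range. Its members included miR-486-3p (0.03), miR-223-3p (0.15) and miR-150-5p (0.18). Of the 18 lists with enough detected members in this comparison, 5 lay outside the middle 95% of random lists.

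The remaining lists lay within it with the blank-spot background and quantile scaling. In other settings the list lowered in colorectal tumours, which shares miR-194 and miR-215, lay outside in 4, the methylation list in 3 and the MYC-repressed list in 2. The first 2 of these counts include both median scalings and spike scaling. Those settings shift all probes of an array alike and give a list the same percentile, so they are not separate checks. The MYC-repressed list lay outside with the offset of 16 (percentile 97.85) and with the blank mean subtracted (99.8). Both keep the blank-spot background and quantile scaling. The list lowered in colorectal tumours also lay outside with the blank mean subtracted (1.23). The epithelial miR-200 family had a median of -0.037, let-7 of -0.003, microRNAs described as raised in colorectal tumours of 0.02, those described as lowered of -0.02, MYC-repressed microRNAs of 0.05, the miR-34 family of -0.01, and microRNAs described as silenced by methylation of -0.008. Only 1 of the 6 miR-34 probes was brighter than the negative controls, miR-34a-5p at 0.49, under the 0.58 reached in simulated unchanged arrays. Of the methylation list, 15 of 45 probes were brighter than the negative controls. The Dlk1-Dio3 cluster (-0.003), the Sfmbt2 cluster (-0.002) and the X-linked testis clusters (-0.008) were also close to 0. Markers of other cell types showed medians of 0.01 for smooth muscle and fibroblasts, 0.01 for neurons and 0.02 for endocrine cells. Brighter than the negative controls were 7 of 23, 1 of 12 and 4 of 7 of these probes. The endothelial list had 2 detected probes, with a median of 0.02 and no percentile.

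The second comparison asked which microRNAs differ in tumour organoids after exposure to the methyltransferase inhibitor. miR-22-3p was higher in treated organoids by a log2 difference of 1.33, from 90.4 to 212 above blank, and was the only one of 1015 probes to reach 2-fold, although it stayed under 2-fold with the median of all probes (0.98) and with the per-spot background column (0.86). miR-711 followed at 0.98 (0.21 to 3.03 over the settings), and miR-34a-5p, a microRNA that p53 induces, at 0.91. miR-27a-3p (0.73), miR-3096a-5p (0.69) and miR-221-3p (0.59) were higher by less. Lower in treated organoids were miR-6412 (-0.80), miR-210-3p (-0.76), miR-194-5p (-0.69), miR-5129-5p (-0.68), miR-3087-5p (-0.65) and miR-192-5p (-0.60), none by 2-fold. miR-215-5p was at 33.4 above blank in untreated and 19.7 in treated tumour organoids, a log2 difference of -0.05. This ranged from -0.36 to 0.41 over the settings, with 0.41 under spike scaling. Both signals are smaller than the offset of 50, which draws their difference towards 0, so its size is uncertain.

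No probe was 2-fold lower. Of the 1015 probes, 157 were detected on 1 of the 2 arrays, with lower bounds of at most 1.15-fold. The largest was that of miR-217-5p, which was 5.13-fold higher in treated organoids with the blank mean subtracted. The counts of higher and lower probes were 9 and 34 in the authors' values, 1 and 3 with the median of commonly detected probes, 0 and 8 with the median of all probes, and 30 and 27 with the per-spot background column, where miR-194-5p (1.46), miR-192-5p (0.27), miR-210-3p (0.27), miR-27a-3p (-0.17) and miR-3096a-5p (-0.41) took the opposite sign. The median over all counted probes was -0.26 in the authors' values and 0.56 under spike scaling, against 0.10 and 0.09 in tumour against wild type.

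By fixed list, the 7 probes of the list of miR-192, miR-194 and miR-215 had a median of -0.05 in treated against untreated organoids, with 5 lower, within the range of random lists, and 0.44 under spike scaling; over probes brighter than the negative controls it was -0.33, under the random range (percentile 0.49). Of 18 lists, 5 lay above the middle 95%, all with small medians. MYC-repressed microRNAs had a median of 0.09 with 22 of 36 probes higher, including miR-22-3p, miR-34a-5p, miR-23a-3p (0.54) and miR-23b-3p (0.50), and the median turned to -0.022 with the median of all probes as scale, where the list stayed above the random range (percentile 99.1). The miR-34 family had a median of 0.10 with 6 of 6 higher, of which only miR-34a-5p was brighter than the negative controls. The let-7 family had a median of 0.06 with 17 of 21 higher, including let-7a-5p (0.21) and let-7d-5p (0.20), and its median turned to -0.023 with the median of all probes (percentile 95.8, within the range) and -0.011 in the authors' values (97.9, above it); let-7a-5p and let-7d-5p turned negative under both median scalings. MicroRNAs described as raised in colorectal tumours had a median of 0.06, with miR-31-5p at 0.47, miR-21a-5p at 0.43 and miR-96-5p at 0.28 (the first turned to -0.15 with the per-spot background column and the last to -0.08 with the median of all probes), and the list turned to -0.035 in the authors' values (percentile 99.0, above the range) and -0.0061 with the median of all probes (92.7, within it). Smooth muscle and fibroblast microRNAs had a median of 0.03, with miR-125b-5p at 0.47 (-0.17 with the per-spot background column), and the list turned to -0.059 in the authors' values, where it stayed above the range (percentile 99.1). It lay within the range with the blank mean subtracted (96.3), above the negative controls (95.4) and with the per-spot background column (79.5).

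MicroRNAs described as silenced by DNA methylation had a median of 0.01 in treated against untreated organoids, with 24 of 40 probes higher, within the range of random lists (percentile 95.4), but above it at the limit of 3 SD (median 0.029, percentile 99.5). Only 15 of the 40 probes were brighter than the negative controls. The imprinted Dlk1-Dio3 cluster had a median of -0.01 with 32 of 81 higher. Medians were 0.10 for the miR-200 family, 0.04 for the miR-17-92 group, 0.003 for microRNAs lowered in colorectal tumours, 0.03 for p53-induced microRNAs, -0.01 for the Sfmbt2 cluster, -0.008 for the miR-290 and miR-302 clusters and 0.001 for the X-linked testis clusters. Those of blood-cell (-0.02), neuronal (-0.03) and endocrine (-0.01) microRNAs were also within the range. Brighter than the negative controls were 20 of 81 Dlk1-Dio3, 8 of 48 Sfmbt2, 0 of 14 X-linked testis and 0 of 11 neuronal probes. Small medians of such dim lists are partly built in by the offset of 50. In other settings the p53-induced list lay above the range in 5 and the miR-17-92 list in 2, the neuronal and Dlk1-Dio3 lists under it in 2 each, and the blood-cell list under it in 1. The 5 include both median scalings and spike scaling, which give a list the same percentile. The single detected endothelial probe was at -0.05.

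The last comparison asked whether probes that differ in tumour organoids lay nearer the wild-type level on the treated array. Of the 13 probes higher in tumour organoids, 7 lay nearer it, and of the 14 lower probes 9 did. Because these probes were chosen by their level on the untreated tumour array, noise on that array alone would raise both shares. These shares turned with the scale, at 20 of 22 higher and 5 of 11 lower probes with the median of commonly detected probes, 29 of 32 and 3 of 10 with the median of all probes, 18 of 37 and 7 of 9 under spike scaling, and 20 of 20 and 23 of 27 with the per-spot background column. Treated organoids still differed 2-fold from wild type for 7 of the 13 and 11 of the 14, including miR-215-5p, miR-194-5p and miR-192-5p. Among the probes each setting counted as higher and lower in tumour organoids, those still 2-fold different were 8 of 22 and 10 of 11 with the median of commonly detected probes, 10 of 32 and 10 of 10 with that of all probes, 29 of 37 and 3 of 9 under spike scaling, and 6 of 20 and 6 of 27 with the per-spot background column, where miR-192-5p was not lower in untreated tumour organoids (0.16). Against wild type, treated tumour organoids had 13 probes at least 2-fold higher and 14 lower of 1027, but 67 and 62 with the blank mean subtracted, 39 and 60 in the authors' values and 67 and 3 under spike scaling. Across 1074 probes the tumour difference and the treatment difference correlated at r = -0.18 (Spearman's rho -0.31). The untreated tumour array enters both with opposite sign, so unchanged arrays simulated with spot noise gave r = -0.61. The covariance was -0.0100 against a simulated -0.00280, and r was -0.74 with the per-spot background column.

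**Figure D2:**
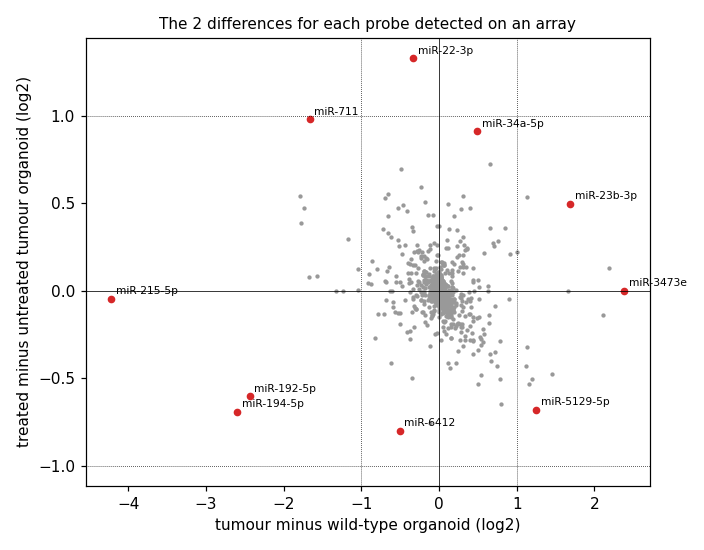
Each point is 1 of 1074 probes detected on at least 1 array, with the log2 difference of tumour minus wild-type organoids on the horizontal axis and of treated minus untreated tumour organoids on the vertical axis; dotted lines mark 2-fold. miR-22-3p is the single probe above the upper dotted line, and miR-215-5p lies at -4.22 on the horizontal axis and -0.05 on the vertical axis.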

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

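The tests of spot noise, of scaling and of the shared tumour array were chosen after the results were seen, as was their repeat without the per-spot background column, while the test on the miR-200 family was written before its value was seen.

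The control spot named S-Probe1014, whose target is not given in the sources used here, read 2930 on the wild-type array, 6569 on the tumour array and 4678 on the treated array, far above the negative controls. Of 22 single-spot control probes of this kind, 6 were brighter than the brightest negative control on all 3 arrays. Negative Control 3 averaged 41.7, 49.3 and 35.3 on the wild-type, tumour and treated arrays. Negative Control 1 averaged 30.6, 33.9 and 25.7, and Negative Control 2 averaged 31.5, 35.5 and 25.8. Each of these means was above the detection limit of its array (29.1, 31.7 and 24.2). A probe called detected may therefore carry no specific signal. With the brightest negative control as the limit, 413, 410 and 408 probes remain.

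The lower signals of miR-192-5p, miR-194-5p and miR-215-5p in tumour organoids exceed spot noise, since the smallest of the 3 differences was 2.44 in size against at most 0.58 in simulated unchanged arrays. A lower share of epithelial RNA would lower the miR-200 family alike, and its 7 brighter probes had a median of -0.089 (SD 0.18). Organoids are epithelial structures, so this value speaks only to RNA of other cells. It cannot address a difference in cell types within the epithelium. The choice of scale and background fits the prediction set for it and stays open, since miR-192-5p stood at 0.16 with the per-spot background column, while miR-215-5p and miR-194-5p stayed lower in every setting. Without that column, the weakest of the 3 differences over all settings was -1.39. Loss of these microRNAs in tumour cells is a hypothesis that remains untested, because culture, hybridisation and group cannot be told apart with 1 array each.

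For miR-22-3p and miR-34a-5p in treated organoids, the smaller difference was 0.91 against at most 0.51 from simulated spot noise. Scale and background also fit the prediction set for them and stay open, since miR-34a-5p was at 0.43 with the per-spot background column, against 0.52 at the least over the other settings. Both probes were higher in every setting. An effect of the drug could not be separated from a difference between cultures.

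For the opposite signs of the tumour and treatment differences, the covariance was -0.009993 against -0.00360 to -0.00221 in 100 draws of simulated spot noise, but r was -0.18 against -0.69 to -0.54, and the draws leave out differences between cultures, so the shared array stays open as their source. A difference in RNA or hybridisation of the untreated tumour array could give the same sign and stays open: the share of tumour-higher probes nearer wild type on treatment was 53.8% (7 of 13, exact 95% interval 25.1% to 80.8%), and that of tumour-lower probes was 64.3% (9 of 14, 35.1% to 87.2%). These intervals treat probes as independent, which they are not. An equal split is not the share expected without a treatment effect, because the probes were chosen on the untreated tumour array. The shares also depend on the scale: 29 of 32 and 3 of 10 with the median of all probes, but 20 of 20 and 23 of 27 with the per-spot background column.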

How the results depend on the processing

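The brightest negative control as a limit and spike scaling were chosen after the data were seen. The fixed plan had named the per-spot background column as the main background, and its use as an alternative came later. The blank-spot background of the main setting, and of the settings built on it, departs from that plan. It was chosen after the properties of the column were seen. Apart from this background, the other settings were planned. No paired analysis was possible because each group has 1 array. With no replicates, a value counts as moved when it shifts by more than 0.14 log2, the spread of a difference between spike spots, and a count when it shifts by more than 1.5 times; the cause was not tested unless stated. The 13 higher and 14 lower tumour probes were the same under the 3 SD limit, detection on every array and the brightest negative control. These settings keep the main values and change only which probes are counted. The offset of 50 keeps probes near background under 2-fold, so the 3 SD and negative-control limits could hardly remove any. All 27 were kept with an offset of 16 and with the blank mean subtracted. Higher and lower probes in tumour organoids numbered 65 and 56 with the blank mean subtracted, 55 and 35 in the authors' values, 33 and 38 at 1.5-fold, 37 and 9 under spike scaling, and 20 and 27 with the per-spot background column; higher ones numbered 22 with the median of commonly detected probes and 32 with that of all probes. In treated organoids they numbered 32 and 20 with the blank mean subtracted, 9 and 34 in the authors' values, 6 and 6 at 1.5-fold, 30 and 27 with the per-spot column, and 0 and 8 with the median of all probes; higher ones numbered 2 with an offset of 16 and 2 under spike scaling, and lower ones 3 with the median of commonly detected probes. Without the offset of 50, dim probes reach larger folds by construction. The median of miR-192, miR-194 and miR-215 in tumour organoids was -2.01 with an offset of 16, -2.52 with the blank mean subtracted, -1.91 in the authors' values, -0.85 under spike scaling and 0.021 with the per-spot column; in treated organoids it was -0.38 in the authors' values, -0.33 above the negative controls and 0.44 under spike scaling. In tumour organoids the miR-17-92 median was -0.25 with the blank mean subtracted, -0.30 above the negative controls and 0.074 under spike scaling. That of the miR-290 and miR-302 clusters was -0.26 with the blank mean subtracted, 0.038 under spike scaling and 4.39e-05 with the per-spot column. Blood-cell microRNAs had 0.39 with the blank mean subtracted, 0.56 in the authors' values and 0.23 under spike scaling. The p53-induced list had -0.45 with an offset of 16, -1.04 with the blank mean subtracted, -0.40 at 3 SD, -0.63 with detection on every array, -0.91 in the authors' values, -0.96 above the negative controls and -0.017 with the per-spot column. In treated organoids let-7 had 0.21 with the blank mean subtracted, -0.023 with the median of all probes, -0.011 in the authors' values and 0.57 under spike scaling; MYC-repressed microRNAs had 0.24 with the blank mean subtracted, -0.022 with the median of all probes and 0.57 under spike scaling. The miR-34 family had 0.26 with an offset of 16, 1.04 with the blank mean subtracted, 0.61 in the authors' values, 0.91 above the negative controls and 0.71 under spike scaling. The colorectal list had 0.21 with the blank mean subtracted, -0.0061 with the median of all probes, -0.035 in the authors' values, 0.21 above the negative controls and 0.58 under spike scaling, and the smooth muscle list had -0.059 in the authors' values and 0.63 under spike scaling. Lists outside the middle 95% of random lists in tumour organoids numbered 3 in the authors' values, 3 above the negative controls and 1 with the per-spot column, against 5; in treated organoids they numbered 8 at 3 SD and 3 with the per-spot column, against 5. With the per-spot column none of the 5 lists of either comparison lay outside: the 1 was the list raised in colorectal tumours, and the 3 were the miR-17-92, Dlk1-Dio3 and p53-induced lists. The correlation of the 2 differences was -0.49 with either median or spike scaling and -0.74 with the per-spot column. Under that column miR-3473b was -1.80, miR-23b-3p -1.32, miR-23a-3p -0.73, miR-192-5p 0.16, miR-378c 0.42, miR-378b 0.025 and miR-215-3p 0.20 in tumour organoids. Of the values of named probes over all settings, 192 moved, 7 reversed from at least 2-fold and 67 stayed within 0.14 in tumour organoids, and 184 moved and 117 stayed in treated organoids, where sign changes of probes under 2-fold count as moved. Probes brighter than the brightest negative control numbered 413, 410 and 408 on the wild-type, tumour and treated arrays, which bounds how many carry signal well over background.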

Other observations

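The tests on precursor arms, gene neighbours and the class of long-known microRNAs were written before their values were seen, although the last was prompted by the list results. The repeats without miR-192, miR-194 and miR-215, and without pairs that share a family number, were chosen after the results were seen.

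The neighbouring genes of miR-182-5p, miR-96-5p and miR-183-5p, named after their values were seen and held in no list of their own, had log2 differences of 0.91, 0.76 and 0.44 in tumour against wild type, and miR-183-3p had 0.18. None reached 2-fold, and the last 2 lie under the 0.58 reached in simulated unchanged arrays. The neighbours miR-221-3p and miR-222-3p had 0.59 and 0.43 in treated against untreated organoids, the second under the 0.51 reached in simulated unchanged arrays, and miR-221-3p was at 0.11 at the least over the settings.

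If differences arise at the locus, neighbouring microRNA genes should differ alike. In tumour against wild type the mean absolute log2 difference between 44 neighbouring pairs was 0.50, lower than in all but 0.34% of shuffled pairings, and 0.38 without miR-192, miR-194 and miR-215. It was 0.54 over the 39 pairs that do not share a family number, lower than in all but 0.87% of shuffled pairings. This fits the prediction but does not single out shared control of loci, since sequence likeness between other probes was not tested. The neighbours miR-194-1-3p (-0.29) and miR-215-5p (-4.22) were far apart, as were miR-194-2-3p (-0.13) and miR-192-5p (-2.44). In treated against untreated organoids the mean was 0.21 over 47 pairs, lower than in all but 1.46% of shuffled pairings. Only 1 probe reached 2-fold there.

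If differences arise at the precursor, both arms should differ alike. The arms of 64 precursors correlated at r = 0.37 in tumour against wild type, above 99.2% of shuffled pairings. This rested on the miR-192 and miR-215 precursors: without them r was 0.14 over 62 precursors, above 86.3% of shuffled pairings. In treated against untreated organoids r was 0.13.

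The 5 lists that lay high in treated organoids hold mostly long-known microRNAs, so a shift of that class as a whole may contribute. Probes numbered under 500 and let-7 had a median of 0.00 against -0.01 for the others, above 99.2% of matched random sets. Against random lists of long-known probes only, 4 of the 5 lists stayed outside the middle 95%, and let-7 did not (percentile 96.8), so a shift of long-known microRNA probes as a class was neither required nor excluded. In tumour against wild type, 3 of the 5 lists stayed outside, and the miR-17-92 (percentile 6.01) and miR-290 and miR-302 (3.10) lists did not.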
